A study of Mus musculus with 8 samples.

How the data were processed

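Total RNA was extracted from wild-type mouse embryonic fibroblasts with an EasyPure RNA kit and made into libraries with a NEBNext Ultra RNA kit, per the labels' protocols. That kit does not mark the strand of a transcript, and the strand setting used for counting is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited values are raw counts per gene, with 1 column per library. The submitters' processing notes name featureCounts from Subread, DESeq2 and the genome build mm10, without versions. The aligner, the annotation release and any read filter are not given in the sources used here. The table holds 54532 Ensembl genes with symbols and coordinates, and 54409 of the identifiers were found in GENCODE M21, of which 53499 had the same start and end. Coordinates are those of the deposited table, counted from 1. Exons were compared with those of other genes, and Cabp7 and Bmp8b, which overlap over 12.9% and 12.2% of their exon length, are uncertain like the genes called so in the text. Because 105 symbols occur more than once, genes were followed by identifier.

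Groups and replicate numbers were taken from the sample titles and treatment labels: 4 groups of 2 libraries, all at day 4. Each library total lay between 10958430 and 11913143 counts. In 1 library of average size, 3 counts correspond to about 0.265 CPM. The floor used here was 3 counts over the 2 libraries of a group, which is a lower mean level. It sets what a count of 0 can exclude. Alkal2, with 3 counts over CFAE+8, had a mean of 0.1275 CPM there. Floors, and the intervals of count ratios, cover counting error only. Genes with low counts were removed with filterByExpr in edgeR 4.0.16 (R 4.3.3), which kept 15470 of the 28024 genes with any count (13589 protein coding) and 99.85% of the counts. Libraries were scaled with TMM factors, and levels are CPM on that scale.

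The main test, set before the data were examined, was edgeR's quasi-likelihood F test with 1 mean per group fitted to all 8 libraries, so that the groups shared 1 estimate of the spread with 4 residual degrees of freedom. The common biological coefficient of variation was 0.0445. A gene was called at a Benjamini-Hochberg adjusted p of 0.05 over all genes tested. The SE of a log2 fold change was taken as the size of the unshrunken coefficient over the square root of F, and 95% intervals came from the t distribution. All 6 comparisons between groups were made. For a gene with no counts in a group, the fold was bounded against 3 counts over the group, and with 1 to 3 counts a ratio with an exact counting interval was given.

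Named genes followed a rule. For the first 3 comparisons (CFAE+8+MSC and CFAE+6 against CFAE+8, and CFAE+8 against MEF) it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in 1 group and both replicates of a group beyond both of the other. Predicted genes, pseudogenes and small RNA genes were passed over. For the other 3 comparisons it took the 4 largest each way. It also took up to 4 members of each gene list per comparison with the smallest adjusted p, and Cdk8, Cdk19 and Ccnc. Outside this rule, Tagln with MSC2530818 against CFAE+8, Axin2, Fn1 and Smad7 in CFAE+6 against CFAE+8, and Postn in CFAE+8+MSC against CFAE+6 were chosen after their values were seen, as were the genes named in the closing observations. Some genes chosen in these ways are not reported here.

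Gene lists were written from general knowledge before the data were examined: targets of TGF-beta, Wnt/beta-catenin, cAMP/CREB, retinoic acid, and serum response and YAP signalling; interferon-stimulated, pro-inflammatory, matrix remodelling, cell cycle, p53 and senescence, cholesterol biosynthesis, glycolysis, oxidative phosphorylation, Hox, Mediator kinase module, core Mediator and housekeeping genes; and markers of fibroblasts, epithelium, extraembryonic endoderm, pluripotent cells, neurons, macrophages, endothelium, skeletal muscle, adipocytes, cartilage and bone, neural crest and glia, and red blood cells. Lists with at least 5 tested members entered camera (limma 3.58.1, preset correlation 0.01), with adjustment over 28 lists in each comparison. The red blood cell list had too few. List members with too few counts in all groups were left out. Only 7 of 22 pluripotency, 13 of 24 epithelial and 16 of 24 neuronal genes were tested. Camera with an estimated correlation, fry and a fit with the replicate number as a block were alternatives. Fry tests whether the genes of a list move one way on balance and does not compare them with other genes.

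The overlap of the MSC2530818 and E-616452 responses was set beside the product of independent lists. It was also set beside 20 simulated pairs of unchanged groups, where both groups of a pair shared the same simulated control libraries. Alternatives for the counts of called genes were DESeq2 size factors and upper-quartile scaling, no filter, a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.2, an added log2 change of at least 1, the replicate block, a fit of only the compared groups, and each replicate left out in turn.

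The steps were tested on simulated data drawn from the real means and library sizes with 200 changed genes. These genes, and those of the random lists below, had a mean of about 1 CPM or more in the reference group. Recovery at lower levels was not measured. In the simulation of CFAE+8+MSC against CFAE+8, 50 of 50 genes raised 4-fold, 43 of 50 raised 2-fold and 33 of 50 raised 1.5-fold were recovered among 14601 tested, with 5 unchanged genes called. In that of CFAE+6 against CFAE+8, 50 of 50, 38 of 50 and 29 of 50 were recovered among 14579, with 14 unchanged genes called. In a separate simulation of the first comparison, camera called 10 of 10 random lists of 20 genes shifted 2-fold and 1 of 10 unshifted lists.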

Results

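RNA was sequenced from wild-type mouse embryonic fibroblasts after 4 days in 1 of 4 media, with 2 libraries per medium and 8 libraries in all. The control cells were kept in fibroblast medium (MEF). The other groups received a cocktail written CFAE, made of CHIR99021 (an inhibitor of GSK-3), Forskolin (an activator of adenylyl cyclase), AM580 (an agonist of the retinoic acid receptor alpha) and the compound labelled EPZ04777 (an inhibitor of the histone methyltransferase DOT1L). To this cocktail was added A-83-01 (CFAE+8), A-83-01 with the CDK8 and CDK19 inhibitor MSC2530818 (CFAE+8+MSC), or E-616452 (CFAE+6). A-83-01 and E-616452 both inhibit the TGF-beta type I receptor. The doses are not given in the labels. The series title places the samples in a chemical screen for cell reprogramming that treats CDK8 as a barrier. Totals ran from 10958430 to 11913143 counts per library, and 15470 of 54532 genes were tested. Levels below are CPM (counts scaled to library size) as mean ± SD with n = 2 in every group, and changes are log2 fold changes ± SE from edgeR with Benjamini-Hochberg adjusted p. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

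The first principal component held 76.3% of the variance and separated MEF from the 3 cocktail groups. The second held 11.4% and separated CFAE+8 from CFAE+8+MSC and CFAE+6. Mitochondrial transcripts took 1.23 ± 0.0233% of counts in MEF, 1.98 ± 0.0318% in CFAE+8, 2.14 ± 0.082% in CFAE+8+MSC and 2.15 ± 0.0926% in CFAE+6. The 2 libraries of each group differed by more than counting noise, with a chi-square per degree of freedom of 1.91 to 2.79 over genes, and none were merged.

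**Figure D1:**
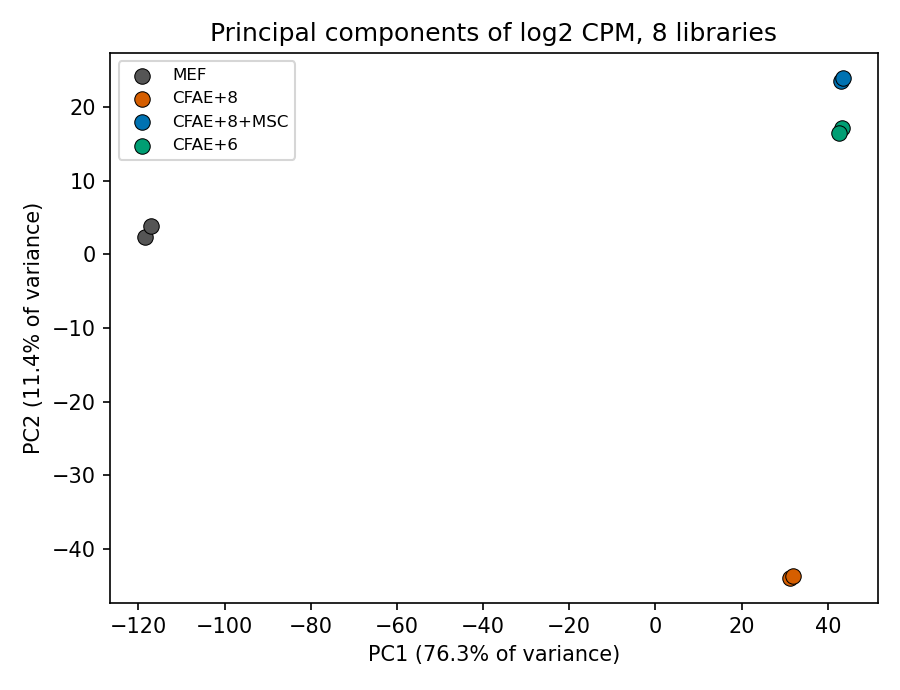
Principal components of log2 CPM over the tested genes, with the first component (76.3% of variance) on the x axis and the second (11.4%) on the y axis, 1 point per library, coloured by group. The CFAE+8 libraries sit at -43.9 and -43.8 on the second axis, while the CFAE+8+MSC libraries sit at 23.6 and 24.0 and the CFAE+6 libraries at 17.2 and 16.6.

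The comparison of CFAE+8 with MEF asked what the cocktail with A-83-01 did by day 4. Stra6, the cell-surface receptor for retinol uptake (ENSMUSG00000032327, mm10 chromosome 9, 58063788 to 58153996), was at 0.236 ± 0.204 CPM in MEF and 745 ± 10.4 CPM in CFAE+8 (adjusted p = 6.4e-33). Axin2, a feedback inhibitor of Wnt signalling (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), rose from 9.14 ± 0.106 to 408 ± 6.73 CPM (log2 change 5.48 ± 0.07, adjusted p = 1.0e-30). Thbs1, the thrombospondin gene and a TGF-beta target (ENSMUSG00000040152, chromosome 2, 118111876 to 118127133), fell from 11660 ± 437 to 258 ± 0.997 CPM (log2 change -5.50 ± 0.04, adjusted p = 7.9e-37). Acta2, smooth muscle actin (ENSMUSG00000035783, chromosome 19, 34241090 to 34255336), fell from 2664 ± 18.7 to 64.4 ± 1.56 CPM (log2 change -5.37 ± 0.05, adjusted p = 2.1e-35). In all, 4762 genes were higher and 4835 lower in CFAE+8, and 1757 and 2093 of these counts also met a change of at least 1 on the log2 scale.

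Several of the genes with the largest changes had no counts in 1 group, so only a bound against a floor of 3 counts over the group can be given. Dkk1, a secreted Wnt inhibitor, was at least 239.9-fold higher in CFAE+8, Cabp7 at least 222.9-fold, Rnf183 at least 87.6-fold and Fam163a at least 84.2-fold. Sp5, a transcription factor gene induced by Wnt signalling, had 1 count in MEF and 1910 in CFAE+8, a ratio of 1742 with a 95% counting interval of 312 to 68850. Nrgn had a ratio of 1734 (593 to 8409), and Cadps, which acts in vesicle secretion, went from 0.278 ± 0.125 to 349 ± 2.08 CPM. In the other direction Upk3b was at least 142-fold lower, Gjb2 at least 90.6-fold and F2rl1 at least 72.4-fold. The bound was 60.7-fold for Lrrn4, 60.3-fold for Fam180a, 55.2-fold for Cyp4a12b and 50.8-fold for Kng2. Anxa8 fell from 148 ± 0.756 to 0.425 ± 0.239 CPM. Aspn, a small matrix proteoglycan, had a ratio of 918 (254 to 7583) and the collagen gene Col10a1 a ratio of 294 (52.3 to 11650), both lower in CFAE+8. These bounds and intervals cover counting error only. Notumos and Myadml2os also stood among the largest rises, at least 337.5-fold and 104.6-fold. Their exons overlap those of other genes over 26.6% and 49.0% of their length, and the library kit does not mark strand, so both are uncertain.

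Of 17 Wnt/beta-catenin target genes tested, 16 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 6.8e-09). Nkd1 went from 6.71 ± 0.0891 to 668 ± 2.55 CPM and Apcdd1 (ENSMUSG00000071847, chromosome 18, 62922327 to 62953195) from 36.95 ± 0.434 to 2756 ± 21.2 CPM. Notum, a secreted enzyme that inactivates Wnt proteins, was 332 ± 4.08 CPM in CFAE+8 and is uncertain because 38% of its exon length overlaps another gene. Of 17 retinoic acid target genes, 11 rose, 2 fell and 4 did not pass (11 and 2 adjusted over the list alone; camera adjusted p = 0.0065, adjusted p = 0.0901 with an estimated correlation). Dhrs3, a retinaldehyde reductase, rose from 22.3 ± 0.672 to 313 ± 11.3 CPM and Cyp26b1, which degrades retinoic acid, from 32.3 ± 4.86 to 402 ± 7.67 CPM. The median change of this list was 0.74, or 0.68 with the genes at 0 counts set to their bound. Among 20 cAMP/CREB target genes, 9 rose, 8 fell and 3 did not pass (9 and 9 adjusted over the list alone; camera adjusted p = 0.805). Pde4d, a cAMP phosphodiesterase, rose from 31.8 ± 2.73 to 193 ± 2.07 CPM, while Cited2 fell from 173 ± 1.63 to 54.7 ± 1.09 CPM.

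Of 26 TGF-beta target genes, 22 fell and 2 rose (22 and 2 adjusted over the list alone; camera adjusted p = 5.9e-09, adjusted p = 0.0516 with an estimated correlation). Ctgf, a matricellular growth factor, fell from 603 ± 1.46 to 8.17 ± 0.0372 CPM. Of 22 serum response and YAP target genes, 18 fell and 3 rose (18 and 3 adjusted over the list alone; camera adjusted p = 2.8e-06). Cavin2, a caveolar coat protein, fell from 374 ± 4.79 to 2.51 ± 0.53 CPM, and Actg2, enteric smooth muscle actin (ENSMUSG00000059430, chromosome 6, 83512905 to 83536265), from 165 ± 6.55 to 1.36 ± 0.0062 CPM. Among 25 matrix remodelling genes, 16 fell, 2 rose and 7 did not pass (16 and 2 adjusted over the list alone; camera adjusted p = 1.0e-04, adjusted p = 0.108 with an estimated correlation). Lox, which crosslinks collagen, fell from 4254 ± 123 to 23.2 ± 0.0748 CPM and the proteoglycan gene Bgn from 3513 ± 41.7 to 182 ± 5.22 CPM, while Mmp11 rose from 66.3 ± 0.603 to 691 ± 12.1 CPM. Fibroblast identity genes divided, with 14 higher, 14 lower and 1 not passing (14 and 14 adjusted over the list alone; camera adjusted p = 0.97). Fbln2 fell from 5079 ± 148 to 502 ± 4.75 CPM and Twist1, a mesenchymal transcription factor gene, rose from 103 ± 0.357 to 994 ± 7.9 CPM.

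Cell cycle genes were higher in CFAE+8, with 35 of 36 past the test and all 36 when adjusted over the list alone (camera adjusted p = 5.6e-12). Histone genes took 0.0232 ± 0.00070% of counts in MEF, 0.00564 ± 0.000356% in CFAE+8, 0.00439 ± 0.0000933% in CFAE+8+MSC and 0.00543 ± 0.000267% in CFAE+6. The DNA topoisomerase gene Top2a rose from 135 ± 3.76 to 311 ± 0.575 CPM and Mcm3, part of the replicative helicase, from 51.0 ± 3.69 to 137 ± 2.49 CPM. All 24 cholesterol biosynthesis genes fell, over all genes and when adjusted over the list alone (camera adjusted p = 3.5e-11). Msmo1 went from 272 ± 11.1 to 64.9 ± 4.15 CPM and Lss from 221 ± 2.72 to 60.3 ± 0.928 CPM. Of 16 neuronal genes, 10 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0057, adjusted p = 0.523 with an estimated correlation), and Sox11 rose from 37.3 ± 3.71 to 399.8 ± 17.0 CPM. Of 15 skeletal muscle genes, 12 fell and 2 rose (12 and 2 adjusted over the list alone; camera adjusted p = 0.0041, adjusted p = 0.0901 with an estimated correlation). Acta1 fell from 60.1 ± 2.49 to 6.04 ± 0.334 CPM and Chrna1 rose from 2.85 ± 0.272 to 27.6 ± 1.2 CPM. Of 10 adipocyte genes 8 fell and 2 did not pass (8 adjusted over the list alone; camera adjusted p = 0.0043, adjusted p = 0.0901 with an estimated correlation), with Lpl, lipoprotein lipase, from 68.75 ± 3.42 to 5.19 ± 0.505 CPM. Col2a1, of the cartilage and bone list, fell from 248 ± 20.3 to 5.06 ± 0.805 CPM, within a list that had 4 genes higher and 6 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.599).

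Of 30 interferon-stimulated genes, 20 fell and 2 rose in CFAE+8 (21 and 2 adjusted over the list alone; camera adjusted p = 1.0e-04, adjusted p = 0.0714 with an estimated correlation). Stat2, a transcription factor of the interferon response, fell from 76.3 ± 3.82 to 18.7 ± 1.53 CPM and Ddx58, an RNA sensor, from 54.3 ± 1.54 to 18.8 ± 3.27 CPM. Macrophage markers fell too: 14 of 15 passed over all genes and over the list alone (camera adjusted p = 1.0e-04, adjusted p = 0.0516 with an estimated correlation), and their summed level went from 245 CPM in MEF to 47.6 CPM in CFAE+8. Lyz2, lysozyme, fell from 124 ± 1.58 to 14.8 ± 0.188 CPM. Pro-inflammatory genes went both ways, with 13 higher and 12 lower over all genes and over the list alone (camera adjusted p = 0.97). Il1rl1, an interleukin receptor gene, fell from 456 ± 0.788 to 10.8 ± 0.952 CPM, while Nfkbia, an inhibitor of NF-kappa-B, rose from 25.6 ± 0.205 to 108 ± 6.55 CPM.

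The other cocktails were compared with MEF in the same way. CFAE+6 had 4890 genes higher and 4876 lower, and CFAE+8+MSC had 4930 higher and 4981 lower. Fezf2, a forebrain transcription factor gene, had no counts in MEF and was at least 280.5-fold higher in CFAE+6 and 296.5-fold higher in CFAE+8+MSC. Dkk1 was at least 225.6-fold and 236.5-fold higher and Cabp7 at least 394-fold and 184.9-fold higher. Map3k7cl was at least 74.8-fold lower in CFAE+6, and Clca3a1 fell from 61.0 ± 0.588 to 0.443 ± 0.0135 CPM in CFAE+8+MSC. Wnt/beta-catenin target genes divided 16 higher and 1 lower in both comparisons (16 and 1 in both adjusted over the list alone; camera adjusted p = 6.4e-09 and 3.0e-09). TGF-beta target genes had 22 lower and 3 higher in CFAE+6 (22 and 3 adjusted over the list alone; camera adjusted p = 2.5e-07, adjusted p = 0.0626 with an estimated correlation) and 19 lower and 5 higher in CFAE+8+MSC (19 and 5 adjusted over the list alone; camera adjusted p = 2.3e-04, adjusted p = 0.148 with an estimated correlation). Cell cycle genes were higher in both, with 32 and 33 of 36 (32 and 34 adjusted over the list alone; camera adjusted p = 1.5e-08 and 2.0e-09), while the histone share was 0.00543% and 0.00439% of counts against 0.0232% in MEF. All 24 cholesterol genes were lower in both (24 in both adjusted over the list alone; camera adjusted p = 2.1e-09 and 2.0e-09). The macrophage list had 15 lower in CFAE+6 and 14 lower in CFAE+8+MSC (15 and 14 adjusted over the list alone; camera adjusted p = 1.1e-05 and 2.4e-05). Tfap2b, a neural crest transcription factor gene with no counts in MEF, was at least 64.5-fold higher in CFAE+6 and 73.3-fold higher in CFAE+8+MSC, against at least 4.56-fold in CFAE+8.

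**Figure D2:**
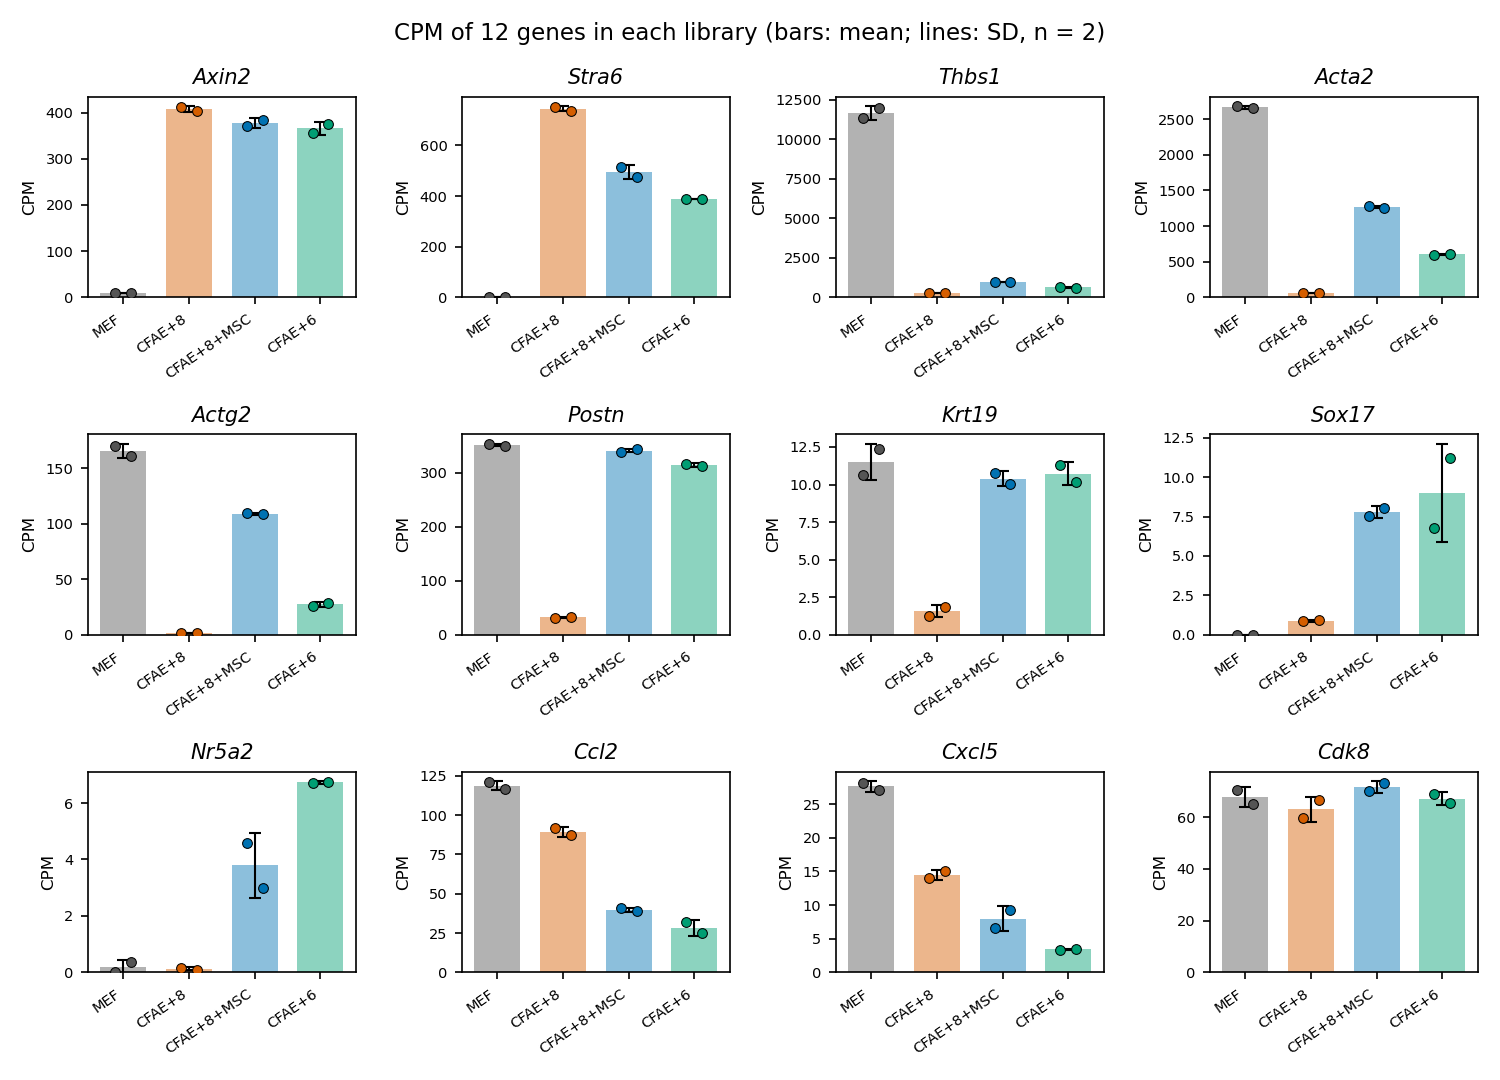
CPM (y axis, linear from 0) of 12 genes in the 4 groups (x axis), with bars at the mean, lines at the SD and points for the 2 libraries of each group. Acta2 stood at 2664 CPM in MEF, 64.4 in CFAE+8, 1268 in CFAE+8+MSC and 602 in CFAE+6, while Cdk8 lay between 63.1 and 71.8 CPM in all 4 groups.

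The comparison of CFAE+8+MSC with CFAE+8 asked what adding the CDK8 and CDK19 inhibitor changed. Myh11, smooth muscle myosin heavy chain (ENSMUSG00000018830, chromosome 16, 14194535 to 14291372), went from 1.62 ± 0.248 to 138 ± 2.11 CPM (log2 change 6.41 ± 0.14, adjusted p = 1.1e-24). Actg2 went from 1.36 ± 0.0062 to 109 ± 0.915 CPM (log2 change 6.31 ± 0.13, adjusted p = 6.3e-25) and Acta2 from 64.4 ± 1.56 to 1268 ± 13.4 CPM (log2 change 4.30 ± 0.04, adjusted p = 1.8e-32). Among named genes the largest fall was in Steap4, a metalloreductase, from 12.9 ± 0.242 to 0.93 ± 0.0911 CPM (log2 change -3.78 ± 0.30, adjusted p = 2.4e-11). In all, 2409 genes were higher and 2129 lower with MSC2530818, and 738 and 250 met the 1-unit log2 threshold as well. DESeq2 gave 1811 higher and 1300 lower, and a test against a 1.2-fold change gave 1294 higher and 731 lower. Leaving out either CFAE+8 replicate lowered both counts as well.

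Other large rises were in Bmp8b, a bone morphogenetic protein gene (0.425 ± 0.118 to 16.4 ± 0.375 CPM), Gsta2, a glutathione transferase (0.17 ± 0.12 to 6.63 ± 0.172 CPM), and Vgf, a secreted neuropeptide precursor (5.57 ± 0.928 to 134 ± 4.36 CPM). Krt20 rose as well (0.212 ± 0.179 to 5.12 ± 0.594 CPM), as did the calcium-binding protein gene Calb1 (0.894 ± 0.185 to 15.9 ± 0.0483 CPM) and Edn1, endothelin (0.384 ± 0.423 to 6.71 ± 0.795 CPM). Alkal2 had 3 counts in CFAE+8 and a ratio of 39.5 (13.2 to 194), and 35.1% of its exon length overlaps another gene, so it is uncertain. Further large falls were in the transcription factor gene Klf2 (7.66 ± 0.516 to 1.01 ± 0.657 CPM), H2-Q4, an MHC class I gene that is uncertain because of close relatives and an overlap over 19.1% of its exon length (5.7 ± 1.59 to 0.848 ± 0.464 CPM), and the scavenger receptor gene Marco (6.55 ± 0.993 to 1.01 ± 0.282 CPM). Levels also fell for the interleukin receptor genes Il31ra (5.4 ± 0.998 to 1.06 ± 0.158 CPM) and Il13ra1 (32.5 ± 0.634 to 9.77 ± 0.139 CPM), Ssh3 (27.3 ± 1.14 to 6.88 ± 1.29 CPM), Mmp23 (30.1 ± 1.34 to 8.39 ± 2.07 CPM) and Pak3 (34.1 ± 5.15 to 9.5 ± 0.648 CPM).

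TGF-beta target genes rose with MSC2530818 while A-83-01 was still present: 21 of 26 were higher and 3 lower over all genes and over the list alone (camera adjusted p = 6.8e-10, adjusted p = 0.0569 with an estimated correlation). Postn, the matrix protein periostin (ENSMUSG00000027750, chromosome 3, 54361109 to 54391037), rose from 32.3 ± 1.48 to 341 ± 3.38 CPM, against 352 ± 2.17 CPM in MEF. Cnn1, calponin, rose from 8.85 ± 0.441 to 119 ± 4.3 CPM and Thbs1 from 258 ± 0.997 to 985 ± 4.82 CPM. Tagln, also of this list, was at 1.49 ± 0.428 and 2.41 ± 1.24 CPM (adjusted p = 0.171, and 0.0308 without CFAE+8+MSC replicate 2) and is uncertain because 67.9% of its exon length overlaps another gene. Serum response and YAP target genes had 15 of 22 higher and 2 lower (16 and 2 adjusted over the list alone; camera adjusted p = 4.3e-06, adjusted p = 0.0569 with an estimated correlation). Myl9, a myosin light chain, rose from 42.6 ± 2.27 to 238 ± 1.96 CPM, whereas Egr1, an immediate early gene of the same list, fell from 202 ± 2.61 to 61.5 ± 0.181 CPM. Of the skeletal muscle genes 8 of 15 were higher and 7 did not pass (8 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.082 with an estimated correlation), among them Acta1 from 6.04 ± 0.334 to 43.1 ± 4.82 CPM. Fibroblast identity genes had 17 of 29 higher and 5 lower (19 and 6 adjusted over the list alone; camera adjusted p = 0.004, adjusted p = 0.112 with an estimated correlation). Fbln2 went from 502 ± 4.75 to 818 ± 1.65 CPM and Thy1 from 1100 ± 8.14 to 1506 ± 20.2 CPM.

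Genes of other cell states also moved. Of 13 epithelial genes, 7 were higher and 6 did not pass (7 adjusted over the list alone; camera adjusted p = 0.0011, adjusted p = 0.082 with an estimated correlation), with Krt19 (ENSMUSG00000020911, chromosome 11, 100140810 to 100148665) from 1.57 ± 0.414 to 10.4 ± 0.495 CPM and Krt18 from 5.79 ± 0.0264 to 19.7 ± 1.46 CPM, both keratins of simple epithelia. Of 16 extraembryonic endoderm genes, 10 were higher and 2 lower over all genes and over the list alone (camera adjusted p = 9.5e-04, adjusted p = 0.0879 with an estimated correlation). The basement membrane collagen gene Col4a1 rose from 196 ± 6.61 to 757 ± 37.6 CPM. Sox17, an endoderm transcription factor gene (ENSMUSG00000025902, chromosome 1, 4490931 to 4497354), rose from 0.893 ± 0.0561 to 7.79 ± 0.364 CPM; it is uncertain because 16.9% of its exon length overlaps another gene. Only 7 of 22 listed pluripotency genes had enough counts to be tested. Of these, 4 rose and 1 fell over all genes and over the list alone (camera adjusted p = 0.0521). Sox2 went from 2.3 ± 0.973 to 9.95 ± 0.258 CPM, and Nr5a2, a nuclear receptor gene, from 3 to 86 counts, a ratio of 29.8 (9.86 to 147). Of 11 neural crest and glial genes, 6 were higher and 5 did not pass (9 higher adjusted over the list alone; camera adjusted p = 4.6e-05, adjusted p = 0.0569 with an estimated correlation). Tfap2b went from 0.639 ± 0.304 to 10.3 ± 0.064 CPM. Neuronal genes had 10 of 16 higher and 3 lower over all genes and over the list alone (camera adjusted p = 0.0082, adjusted p = 0.347 with an estimated correlation). Gap43 went from 309 ± 4.61 to 196 ± 3.92 CPM. Endothelial genes had 4 of 8 higher and 4 not passing (5 higher adjusted over the list alone; camera adjusted p = 0.019, adjusted p = 0.165 with an estimated correlation). The VEGF receptor gene Kdr went from 20.6 ± 1.06 to 44.6 ± 1.51 CPM. Hox genes had 8 of 32 lower and 3 higher over all genes and over the list alone (camera adjusted p = 0.0094, adjusted p = 0.112 with an estimated correlation). Hoxb9 went from 134 ± 0.67 to 105 ± 1.53 CPM and Hoxc13 from 0.978 ± 0.176 to 3.44 ± 0.52 CPM.

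Of 28 pro-inflammatory genes, 18 fell and 7 rose with MSC2530818 over all genes and over the list alone (camera adjusted p = 9.3e-04, adjusted p = 0.151 with an estimated correlation). Ccl2, a monocyte chemokine (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453), fell from 89.4 ± 3.29 to 39.8 ± 1.47 CPM and Csf1, a macrophage growth factor, from 120 ± 0.366 to 58.6 ± 3.27 CPM. The collagenase gene Mmp13, of the same list, rose from 65.1 ± 4.52 to 173 ± 5.06 CPM and Mmp9 from 28.7 ± 1.75 to 70.7 ± 3.84 CPM. Of 30 interferon-stimulated genes, 6 fell and 24 did not pass (6 adjusted over the list alone; camera adjusted p = 0.0082, adjusted p = 0.121 with an estimated correlation). Ddx58 went from 18.8 ± 3.27 to 10.2 ± 1.94 CPM. Macrophage markers moved with these groups: 3 of 15 fell and 12 did not pass (3 adjusted over the list alone; camera adjusted p = 0.0082, adjusted p = 0.1 with an estimated correlation), and their summed level was 47.6 CPM in CFAE+8 and 27.8 CPM in CFAE+8+MSC. Lyz2 fell from 14.8 ± 0.188 to 3.61 ± 0.89 CPM, a large part of the fall in that sum. Only 7 of the 15 markers reached a mean of 1 CPM in CFAE+8.

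Cell cycle genes were lower with MSC2530818 in 17 of 36 cases and 19 did not pass (18 lower adjusted over the list alone; camera adjusted p = 2.8e-04, adjusted p = 0.0569 with an estimated correlation). The proliferation marker gene Mki67 went from 175 ± 4.29 to 123 ± 4.68 CPM, and the histone share of counts was 0.00564% and 0.00439%. Of 22 p53 and senescence genes, 11 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.0033, adjusted p = 0.082 with an estimated correlation). Igfbp5 rose from 74.7 ± 0.581 to 275 ± 8.65 CPM and Pmaip1, a pro-apoptotic p53 target, from 63.1 ± 1.16 to 172 ± 1.4 CPM. Cholesterol biosynthesis genes were higher in 12 of 24 cases and 12 did not pass (14 higher adjusted over the list alone; camera adjusted p = 1.1e-05, adjusted p = 0.0569 with an estimated correlation). Cyp51 went from 146 ± 7.04 to 228 ± 0.0183 CPM. Glycolysis genes had 7 of 21 lower and 1 higher (8 and 1 adjusted over the list alone; camera adjusted p = 0.0282, adjusted p = 0.151 with an estimated correlation). Hk1 went from 95.8 ± 1.94 to 71.3 ± 1.18 CPM. The cAMP/CREB list had 10 of 20 higher and 4 lower (11 and 5 adjusted over the list alone; camera adjusted p = 0.0483, adjusted p = 0.267 with an estimated correlation). Rgs2 went from 9.95 ± 0.075 to 31.1 ± 0.453 CPM.

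The remaining lists were not called by camera. Wnt/beta-catenin targets had 9 of 17 higher and 4 lower (9 and 5 adjusted over the list alone; camera adjusted p = 0.236), among them Bmp4 from 86.9 ± 4.3 to 194 ± 3.57 CPM and Apcdd1 from 2756 ± 21.2 to 1953 ± 41.1 CPM. Retinoic acid targets had 5 higher and 6 lower over all genes and over the list alone (camera adjusted p = 0.623). The receptor gene Rarg went from 250.3 ± 6.56 to 122 ± 0.618 CPM and Stra6 from 745 ± 10.4 to 495 ± 28.2 CPM. Matrix remodelling genes had 10 higher and 10 lower over all genes and over the list alone (camera adjusted p = 0.673). Timp1 went from 149 ± 2.36 to 57.5 ± 0.993 CPM and Fbln5 from 31.1 ± 0.623 to 65.7 ± 5.62 CPM. The adipocyte list had 1 higher and 1 lower (camera adjusted p = 0.664), the cartilage and bone list 5 higher and 3 lower (0.304) and the housekeeping list 3 higher and 3 lower (0.759), with the same counts when adjusted over the list alone. The oxidative phosphorylation list had 2 higher and 1 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.623). The 11 red blood cell genes listed had too few counts to be tested.

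Transcripts of the inhibited kinases were examined in each group. Cdk8 (ENSMUSG00000029635, chromosome 5, 146231230 to 146302874) was at 68.0 ± 3.88 CPM in MEF, 63.1 ± 4.77 in CFAE+8, 71.8 ± 2.26 in CFAE+8+MSC and 67.2 ± 2.5 in CFAE+6. Its log2 change with MSC2530818 was 0.18 ± 0.07 (95% interval 0.03 to 0.34, edgeR adjusted p = 0.0613). An edgeR fit of only the compared groups gave 0.19 (adjusted p = 0.0433), and the change was 0.27 without CFAE+8 replicate 2. Cdk19 fell from 23.6 ± 0.589 to 18.6 ± 2.82 CPM with MSC2530818 (adjusted p = 0.0316), and it was 18.0 ± 0.117 CPM in CFAE+6. This call was lost without CFAE+8+MSC replicate 1 (adjusted p = 0.385), without CFAE+8 replicate 1 (0.153) or 2 (0.0877) and with DESeq2 (0.143). Ccnc, the cyclin partner of both kinases, was at 19.2 ± 2.13 and 19.7 ± 1.46 CPM (adjusted p = 0.858). Of the 7 Mediator kinase module genes, 3 were lower and 4 did not pass (1 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.623), and of 25 core Mediator genes 1 was higher and 2 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.304). Med13l fell from 91.8 ± 0.298 to 77.2 ± 6.56 CPM (adjusted p = 0.0046, and 0.149 without CFAE+8+MSC replicate 1) and Med16 from 34.6 ± 2.75 to 23.4 ± 2.22 CPM.

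CFAE+6 was compared with CFAE+8 to set 2 inhibitors of the same receptor side by side at the same day, with E-616452 in place of A-83-01. The doses are not given in the labels, so the compounds were not compared at known matched doses. Among named genes the largest rise was in Nr5a2 (ENSMUSG00000026398, chromosome 1, 136842571 to 136960448), from 3 counts with A-83-01 to 155 with E-616452, a ratio of 52.7 (17.7 to 258). Acta2 rose from 64.4 ± 1.56 to 602 ± 6.46 CPM, a difference of 3.22 with a 95% interval of 3.13 to 3.31 (adjusted p = 3.5e-29), and Postn differed by 3.29 (3.16 to 3.41). Marco fell from 6.55 ± 0.993 to 0.174 ± 0.0036 CPM (log2 change -5.15 ± 0.50, adjusted p = 3.3e-09). In all, 2215 genes were higher and 1901 lower with E-616452, and 691 and 171 met the 1-unit log2 threshold. DESeq2 gave 1569 higher and 1201 lower, and a test against a 1.2-fold change gave 1085 higher and 569 lower. Both counts also fell without either CFAE+8 replicate.

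Other large rises were in Calb1 (0.894 ± 0.185 to 25.4 ± 2.42 CPM), Actg2 (1.36 ± 0.0062 to 27.3 ± 2.32 CPM), Aldh3a1 (0.383 ± 0.0584 to 6.37 ± 0.911 CPM), and Myh11 (1.62 ± 0.248 to 26.2 ± 1.16 CPM). Rises of this kind were also seen in Gdf7 (0.383 ± 0.0584 to 5.53 ± 0.913 CPM), Tfap2b (0.639 ± 0.304 to 9.04 ± 0.679 CPM), Bmp8b (0.425 ± 0.118 to 5.6 ± 0.0677 CPM), Vgf (5.57 ± 0.928 to 67.2 ± 6.28 CPM) and the Wnt antagonist gene Sfrp5 (1.19 ± 0.837 to 12.04 ± 2.94 CPM). Falls were seen in Steap4 (12.9 ± 0.242 to 1.04 ± 0.144 CPM), Klf2 (7.66 ± 0.516 to 1.13 ± 0.146 CPM), Il31ra (5.4 ± 0.998 to 1.13 ± 0.0235 CPM) and Wisp2 (8.89 ± 0.862 to 1.96 ± 0.225 CPM). Further falls were in the neutrophil chemokine genes Cxcl5 (14.5 ± 0.716 to 3.43 ± 0.113 CPM) and Cxcl1 (10.97 ± 1.15 to 2.92 ± 1.23 CPM), F5 (7.27 ± 0.214 to 2.2 ± 1.73 CPM) and Pak3 (34.1 ± 5.15 to 10.8 ± 0.778 CPM).

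Of 26 TGF-beta target genes, 15 were higher and 8 lower with E-616452 (16 and 8 adjusted over the list alone; camera adjusted p = 8.0e-04, adjusted p = 0.122 with an estimated correlation). Thbs1 differed by 1.30 (1.22 to 1.37), whereas Fn1, fibronectin, differed by -0.53 (adjusted p = 7.0e-14). For Smad7, an inhibitory SMAD induced by TGF-beta, the difference was -0.28 (-0.43 to -0.14). The receptor inhibitors also differed outside this list, as in Stra6 (-0.94, interval -1.04 to -0.84), while Axin2 differed by -0.16 (-0.25 to -0.06; adjusted p = 0.0143). The Axin2 call was lost without CFAE+8 replicate 1 (adjusted p = 0.146) or 2 (0.0627) and without CFAE+6 replicate 1 (0.150). Serum response and YAP targets had 10 of 22 higher and 5 lower (12 and 5 adjusted over the list alone; camera adjusted p = 0.0155, adjusted p = 0.1 with an estimated correlation). Myl9 went from 42.6 ± 2.27 to 130.4 ± 0.502 CPM. Epithelial genes had 7 of 13 higher and 1 lower over all genes and over the list alone (camera adjusted p = 1.0e-04). Krt19 went from 1.57 ± 0.414 to 10.7 ± 0.776 CPM and the desmosome gene Dsp from 200.3 ± 2.24 to 140.5 ± 3.46 CPM. Skeletal muscle genes had 7 of 15 higher and 8 not passing (10 higher adjusted over the list alone; camera adjusted p = 4.2e-05). Myh3 went from 3.23 ± 0.346 to 12.2 ± 0.975 CPM. Neural crest and glial genes had 7 of 11 higher and 4 not passing (8 higher adjusted over the list alone; camera adjusted p = 1.2e-05). Extraembryonic endoderm genes had 8 of 16 higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 2.5e-04, adjusted p = 0.0632 with an estimated correlation). Col4a1 went from 196 ± 6.61 to 616 ± 12.97 CPM. Pluripotency genes had 4 of 7 higher and 1 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.0438, adjusted p = 0.274 with an estimated correlation), and neuronal genes 8 of 16 higher and 1 lower over all genes and over the list alone (camera adjusted p = 0.0066, adjusted p = 0.385 with an estimated correlation).

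Pro-inflammatory genes fell in 18 of 28 cases and 1 rose with E-616452 (18 and 3 adjusted over the list alone; camera adjusted p = 1.1e-08, adjusted p = 0.0614 with an estimated correlation). Ccl2 fell from 89.4 ± 3.29 to 28.4 ± 5.14 CPM, Mmp10 from 49.1 ± 0.886 to 18.0 ± 0.732 CPM and Nfkbia from 108 ± 6.55 to 60.1 ± 1.08 CPM. Macrophage markers had 2 of 15 lower and 13 not passing (2 adjusted over the list alone; camera adjusted p = 0.0093, adjusted p = 0.0972 with an estimated correlation), and their summed level was 28.8 CPM in CFAE+6 against 47.6 CPM in CFAE+8. Cell cycle genes fell in 20 of 36 cases and 16 did not pass (24 adjusted over the list alone; camera adjusted p = 1.4e-07). Mki67 went from 175 ± 4.29 to 98.1 ± 1.86 CPM. Glycolysis genes fell in 15 of 21 cases and 6 did not pass (15 adjusted over the list alone; camera adjusted p = 6.7e-06). The lactate transporter gene Slc16a3 went from 43.6 ± 2.36 to 19.7 ± 0.818 CPM; Gapdh, with many pseudogene copies, counted 22.6 ± 0.86 and 12.3 ± 0.994 CPM and is uncertain. The p53 and senescence list had 16 of 22 higher and 1 lower (17 and 1 adjusted over the list alone; camera adjusted p = 1.4e-06). Igfbp5 went from 74.7 ± 0.581 to 389 ± 24.9 CPM. Cholesterol biosynthesis genes had 17 of 24 higher and 7 not passing (19 higher adjusted over the list alone; camera adjusted p = 2.8e-06). Sqle went from 111 ± 6.34 to 144 ± 3.51 CPM. Hox genes had 9 of 32 lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 8.0e-04, adjusted p = 0.0632 with an estimated correlation). Interferon-stimulated genes had 3 lower and 2 higher of 30 (2 and 1 adjusted over the list alone; camera adjusted p = 0.224), and fibroblast identity genes 12 higher and 4 lower of 29 (12 and 5 adjusted over the list alone; camera adjusted p = 0.05001). Lum went from 92.4 ± 2.41 to 216 ± 22.4 CPM.

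The responses to MSC2530818 and to E-616452, both measured against the same 2 CFAE+8 libraries, overlapped. The second of these is also a response to the loss of A-83-01. Of the genes called, 1580 were higher in both and 1221 lower in both, against 344.9 and 262 for independent lists of these sizes, and 38 went opposite ways. Across the 15470 tested genes, which are not independent replicates, the log2 changes correlated with r = 0.78 and a covariance of 0.341. In 20 simulated pairs of unchanged groups, both were set against the same simulated control libraries, drawn from the CFAE+8 means. There r averaged 0.48 (largest 0.517) and the covariance 0.0408, so the observed covariance exceeded the simulated value by 0.2998. The simulated pairs shared on average 0.1 genes called higher in both. Few genes were called at all in these unchanged groups, so this count does not give the overlap to expect among the genes called here. The 2 control libraries cannot be divided with 2 on each side, and part of the excess may come from the shared controls. On log2 CPM, r was 0.801 with the shared libraries and 0.627 and 0.634 against separate single CFAE+8 libraries, and the covariance was 0.243 shared and 0.210 and 0.212 separate.

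**Figure D3:**
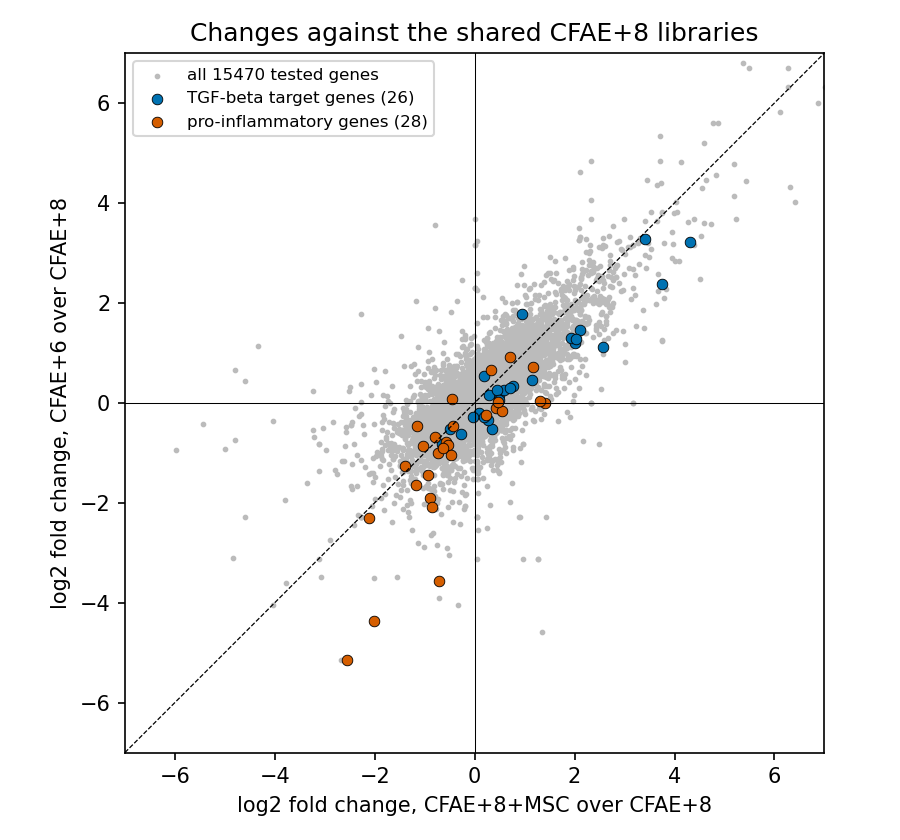
Log2 fold change of CFAE+8+MSC over CFAE+8 (x axis) against that of CFAE+6 over CFAE+8 (y axis) for 15470 tested genes, 1 point per gene, with 26 TGF-beta target genes and 28 pro-inflammatory genes coloured and a dashed line of equal change; both axes end at 7 in either direction, which leaves 4 genes outside. Changes correlated with r = 0.78 across genes, where simulated unchanged groups that shared simulated controls averaged 0.48.

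CFAE+8+MSC and CFAE+6 were compared directly to show where these 2 cocktails differed. Myh11 was 138 ± 2.11 CPM with MSC2530818 and 26.2 ± 1.16 CPM in CFAE+6 (log2 change 2.40 ± 0.09, adjusted p = 3.0e-18), Actg2 109 ± 0.915 and 27.3 ± 2.32 CPM (2.00 ± 0.08, adjusted p = 1.2e-17) and Acta2 1268 ± 13.4 and 602 ± 6.46 CPM (1.08 ± 0.04, adjusted p = 3.0e-18). Postn did not pass, with 341 ± 3.38 and 315 ± 3.54 CPM (adjusted p = 0.127). There were 961 genes higher with MSC2530818 and 660 lower, of which 84 and 59 met the 1-unit log2 threshold. Of the 2801 genes called the same way against CFAE+8, 514 differed here, 335 higher and 179 lower with MSC2530818. DESeq2 gave 655 higher and 342 lower, and leaving out any 1 library of these groups lowered both counts as well. A test against a 1.2-fold change gave 190 higher and 89 lower.

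Other genes named by the size of the difference were mt-Nd4l, a mitochondrial subunit of complex I (ENSMUSG00000065947, MT 9877 to 10173), with 28.8 ± 3.25 CPM in CFAE+8+MSC and 3.73 ± 0.659 CPM in CFAE+6, and Foxs1, with 8.59 ± 0.513 and 2.3 ± 0.136 CPM. Lower with MSC2530818 were Ldoc1 (3.58 ± 0.203 against 10.1 ± 1.45 CPM), Rps27a (162 ± 1.02 against 418 ± 37.6 CPM), Sfrp5 (5.18 ± 0.472 against 12.04 ± 2.94 CPM) and Amelx (2.83 ± 0.0385 against 6.46 ± 0.664 CPM). Without CFAE+6 replicate 2 the adjusted p was 0.0599 for Sfrp5 and 0.083 for Amelx, and DESeq2 gave 0.0616 for Amelx. Rps27a (ENSMUSG00000020460, chromosome 11, 29545846 to 29548109) has pseudogene copies that can share its reads and is uncertain. The difference in mt-Nd4l is uncertain too, because the mitochondrial gene mt-Nd4 did not move with it (log2 change -0.016 ± 0.039).

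TGF-beta target genes were higher with MSC2530818 than with E-616452 in 19 of 26 cases and lower in 2 (22 and 2 adjusted over the list alone; camera adjusted p = 6.1e-15, adjusted p = 0.0582 with an estimated correlation). Fn1 was 3056 ± 63.3 CPM against 1671 ± 3.57, and Tnc, a matrix glycoprotein, 2021 ± 46.1 against 1259 ± 37.0 CPM. Serum response and YAP targets had 13 of 22 higher and 1 lower (14 and 2 adjusted over the list alone; camera adjusted p = 1.2e-06, adjusted p = 0.0582 with an estimated correlation). Myl9 was at 238 ± 1.96 against 130.4 ± 0.502 CPM. Vcl, vinculin, was at 346 ± 7.36 against 208 ± 9.74 CPM, and it is uncertain because 25.5% of its exon length overlaps another gene. Pro-inflammatory genes had 14 of 28 higher and 2 lower (16 and 3 adjusted over the list alone; camera adjusted p = 4.6e-06, adjusted p = 0.215 with an estimated correlation). Mmp13 was at 173 ± 5.06 against 64.9 ± 0.798 CPM and Ccl7 at 68.9 ± 6.52 against 47.9 ± 0.752 CPM. Macrophage markers had 1 higher and 1 lower over all genes and over the list alone (camera adjusted p = 0.481) and summed levels of 27.8 and 28.8 CPM. Glycolysis genes had 5 of 21 higher and 16 not passing (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0116, adjusted p = 0.215 with an estimated correlation). Slc16a3 was at 36.9 ± 2.5 against 19.7 ± 0.818 CPM. Cell cycle genes had 3 of 36 higher and 33 not passing (3 higher adjusted over the list alone; camera adjusted p = 0.0329, adjusted p = 0.215 with an estimated correlation), and adipocyte genes 2 of 10 lower and 8 not passing (4 lower adjusted over the list alone; camera adjusted p = 0.0329, adjusted p = 0.237 with an estimated correlation). Oxidative phosphorylation genes had 2 of 27 lower and 25 not passing (2 lower adjusted over the list alone; camera adjusted p = 0.0213, adjusted p = 0.388 with an estimated correlation).

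With an estimated correlation between genes in place of the preset value, camera calls held for 7 of 15 lists in CFAE+6 against CFAE+8 (epithelial, cell cycle, p53 and senescence, cholesterol, glycolysis, skeletal muscle, neural crest and glial) and for 4 of 12 in CFAE+8 against MEF (Wnt/beta-catenin, serum response and YAP, cell cycle, cholesterol). They held for 5 of 13 in CFAE+6 against MEF, the same 4 lists and the macrophage list, and for 6 of 10 in CFAE+8+MSC against MEF, those 5 and the interferon list. The smallest adjusted p was 0.0569 for CFAE+8+MSC against CFAE+8 and 0.0582 for CFAE+8+MSC against CFAE+6. A larger correlation does not explain every lost call. With MSC2530818 against CFAE+8, the estimated correlation was -0.025 for the cholesterol list and -0.00076 for the serum response and YAP list, below the preset 0.01. Their unadjusted camera p still went from 1.2e-06 to 0.0058 and from 3.1e-07 to 0.0049. The estimated and preset settings therefore differ in more than the correlation. A call lost with an estimated correlation is not by itself evidence that the genes of a list are correlated. The median, the mean and the camera direction differed in sign for some lists that camera did not call. With MSC2530818 against CFAE+8 these were the retinoic acid, Mediator kinase module, adipocyte and housekeeping lists, and with CFAE+6 against CFAE+8 the retinoic acid and core Mediator lists. Against MEF they were the fibroblast, extraembryonic endoderm, endothelial and neural crest lists in CFAE+8, the fibroblast and endothelial lists in CFAE+6, and the fibroblast, core Mediator, p53 and housekeeping lists in CFAE+8+MSC. Between CFAE+8+MSC and CFAE+6 they were the macrophage and housekeeping lists.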

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

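All alternatives here were set before the data were examined. No gene called by both the main test and the replicate block changed sign in any comparison. Adding a log2 change of at least 1 left 738 higher and 250 lower (CFAE+8+MSC against CFAE+8), 691 and 171 (CFAE+6 against CFAE+8), 1757 and 2093 (CFAE+8 against MEF), 1905 and 2093 (CFAE+6 against MEF), 1979 and 2139 (CFAE+8+MSC against MEF) and 84 and 59 (CFAE+8+MSC against CFAE+6), by construction a stricter rule. Testing against a fold of 1.2 gave 1294 and 731, 1085 and 569, and 190 and 89 in the first, second and last of these. DESeq2 gave 1811 higher and 1300 lower, 1569 and 1201, and 655 and 342 there. The cause was not tested.

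Leaving out each replicate in turn gave 1364 to 1542 lower with MSC2530818 (1386 without CFAE+8 replicate 1, 1364 without replicate 2), and 1184 to 1500 lower in CFAE+6 against CFAE+8 (1260 and 1184 without the same libraries). Between CFAE+8+MSC and CFAE+6 it gave 584 to 886 higher (584 without CFAE+6 replicate 2) and 349 to 565 lower (349 without CFAE+8+MSC replicate 1, 363 without CFAE+6 replicate 2). The counts of genes higher than in CFAE+8 also fell in each of these fits. Counts are given here for results that at least 1 such setting moved by more than 1.5-fold. A lone sample was assumed to vary like the other groups, and fewer samples were fitted.

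The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.021 to 0.051. With the replicate block, 4473 of 4538, 4062 of 4116, 9526 of 9597, 9714 of 9766, 9861 of 9911 and 1603 of 1621 calls were kept in the 6 comparisons, and the glycolysis list in CFAE+6 against MEF went from an adjusted p of 0.0452 to 0.057. Block lists called were 18, 15, 12, 12, 10 and 7.

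Lists called by camera with an estimated correlation numbered 0 (CFAE+8+MSC against CFAE+8; 12 at an unadjusted p of 0.05, 22 by fry), 7 (CFAE+6 against CFAE+8), 4 (CFAE+8 against MEF), 5 (CFAE+6 against MEF), 6 (CFAE+8+MSC against MEF) and 0 (CFAE+8+MSC against CFAE+6; 5 unadjusted, 9 by fry). Fry, another question, called 22, 27 and 25 lists in the comparisons with MEF. It gave the opposite direction for pro-inflammatory genes in CFAE+8 against MEF (adjusted p = 0.0171), fibroblast identity genes in CFAE+6 against MEF (0.0261) and p53 and senescence genes in CFAE+8+MSC against MEF (3.7e-04); the cause was not tested. Genes shared by both responses at the log2 threshold were 479 higher and 72 lower, and with separate controls r was 0.627 and 0.634. Other scalings moved the share of higher calls by less than 5 points. Of 193 results for named genes, 10 changed their side of the threshold in at least 1 alternative, with 17 calls lost and 3 gained in 2509 alternative fits and 0 reversed; Smad7, Sqle and Hoxb9 lost theirs only against a fold of 1.2. Most named genes were chosen for large changes or small adjusted p in the main test, so this stability partly follows from that choice. Over all calls, DESeq2 kept 3111 of 4538 in CFAE+8+MSC against CFAE+8 and 997 of 1621 in CFAE+8+MSC against CFAE+6. Depth limits genes near the floor of 3 counts over a group, where a count of 0 cannot exclude expression.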

Other observations

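The smooth muscle, imprinted and MHC class I gene lists described here, and the tests of a partial return toward fibroblast medium, of mt-Nd4l and of macrophages, were chosen after the results were seen. The tests of shared control libraries, of Rps27a copies and of embryo pools were set before. Because the 3 lists were chosen this way, their counts of genes called by edgeR are not independent evidence, and no test of a list as a whole is given.

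With MSC2530818, 19 of 21 tested smooth muscle contractile genes were higher than in CFAE+8 and 2 did not pass, with Lmod1, leiomodin, from 1.96 ± 0.713 to 30.5 ± 0.935 CPM and Mylk, myosin light chain kinase, from 23.3 ± 0.708 to 63.8 ± 1.99 CPM. Myocd, the cofactor that drives smooth muscle genes, was at 3.49 ± 0.257 and 3.68 ± 0.676 CPM (edgeR adjusted p = 0.882). In CFAE+6, 17 of 21 were higher than in CFAE+8, while CFAE+8 had 20 of 21 lower than MEF and 1 higher, Myocd, which rose from 0.792 ± 0.0453 to 3.49 ± 0.257 CPM (edgeR adjusted p = 2.1e-05). Between CFAE+8+MSC and CFAE+6, 18 of 21 were higher with MSC2530818.

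Imprinted genes, expressed from 1 parental copy in at least some tissues, were mostly lower in CFAE+8 than in MEF, with 23 of 34 lower and 4 higher. In CFAE+6, 14 were higher and 4 lower than in CFAE+8, and in CFAE+8+MSC 3 were higher and 5 lower than in CFAE+6. With MSC2530818, 15 were higher and 5 lower than in CFAE+8. Igf2, a fetal growth factor, rose from 57.4 ± 3.33 to 156 ± 6.48 CPM, Zim1 from 16.5 ± 0.255 to 98.1 ± 4.19 CPM, Peg3 from 273 ± 16.0 to 625 ± 7.21 CPM and H19 from 2023 ± 36.0 to 2992 ± 150 CPM, and 64.5% of the exon length of Igf2 overlaps another gene, so it is uncertain. Nnat fell from 156 ± 9.86 to 93.5 ± 4.27 CPM. Among 16 genes of MHC class I and antigen presentation, 10 fell with MSC2530818 and 6 did not pass. B2m fell from 180.2 ± 0.701 to 110.3 ± 13.6 CPM, H2-D1 from 105 ± 2.16 to 68.8 ± 0.918 CPM and Tapbp, which loads peptides, from 33.1 ± 1.11 to 16.7 ± 0.114 CPM, with 29.0% of its exon length in overlap and so uncertain. In CFAE+6, 6 of these genes were lower and 1 higher than in CFAE+8. In the same comparisons the macrophage markers had 3 of 15 and 2 of 15 lower, and their summed level was 47.6 CPM in CFAE+8, 27.8 CPM in CFAE+8+MSC and 28.8 CPM in CFAE+6.

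The responses to MSC2530818 and E-616452 were similar across genes. Chance values particular to a single CFAE+8 library are argued against as the whole cause, since the correlation against separate single CFAE+8 libraries was still 0.627. A chance deviation common to both CFAE+8 libraries would pass this test and stays open, because the labels do not say whether they came from separate cultures. A plain return of both toward fibroblast medium is argued against too, because 56.4% of the 2801 genes called the same way moved toward their level in MEF. With 1 library per group the share was 56.2% to 56.8% over 16 choices, a spread between libraries only, since genes are not independent replicates. A hypothesis that stays open is that adding MSC2530818 and putting E-616452 in place of A-83-01 act on an overlapping set of pathways; the loss of A-83-01 is part of the second change, and doses and other compounds that could test it were not analysed here.

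Some single genes stood apart between the cocktails. More mitochondrial RNA is argued against for mt-Nd4l, since the other tested mitochondrial protein genes had a median log2 change of 0.032 between CFAE+8+MSC and CFAE+6. Those genes ran from -1.162 ± 0.453 for mt-Nd3 to 1.114 ± 0.903 for mt-Atp8. For mt-Nd4 the change was -0.016 ± 0.039, so the difference in mt-Nd4l stays uncertain. A move of counted reads between Rps27a and its pseudogene copies is argued against, because their summed CPM was still 2.41-fold higher in CFAE+6 than in CFAE+8. Whether reads that match several loci were counted is not given; if not, they are missing from that sum, so a change in the share left out stays open. Whether the fibroblasts came from different embryo pools could not be decided: the largest difference among Xist, Ddx3y, Eif2s3y, Kdm5d and Uty was 1.45-fold, for Xist, between the bounds set beforehand. Other technical sources for these genes, and any biological one, were not tested.

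Of 28 pro-inflammatory genes, 18 were lower and 1 higher in CFAE+6 than in CFAE+8 (18 and 3 adjusted over the list alone; camera adjusted p = 1.1e-08, adjusted p = 0.0614 with an estimated correlation). In CFAE+8+MSC 18 were lower and 7 higher, over all genes and adjusted over the list alone (camera adjusted p = 9.3e-04, adjusted p = 0.151 with an estimated correlation). Of 15 macrophage markers, 2 and 3 were lower and the others did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0093 and 0.0082, adjusted p = 0.0972 and 0.1 with an estimated correlation). The called lower pro-inflammatory genes lost 7.74 times the whole summed CPM of these markers of CFAE+8 in CFAE+6 and 6.73 times in CFAE+8+MSC, but the pro-inflammatory RNA that a macrophage holds for each CPM of markers was not measured. Only 7 of the 15 markers reached a mean of 1 CPM in CFAE+8, so their sum rests on few genes. Fewer macrophages and lower expression in the fibroblasts cannot be told apart, and the second was not tested.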
